A study of Mus musculus with 12 samples.

How the data were processed

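Expression was measured in 12 RNA samples from 6 lines of primary mouse embryonic fibroblasts, each line cultured for 6 h at 21% or 0.1% O2, with 1 Affymetrix Mouse430_2 array (biotin label, 1 colour) per sample. Per the labels, the embryos were at e14.5, Cre recombinase was delivered by adenovirus, and the cultures were kept at 37 °C with 5% CO2. The deposited values are probe set signals in units of intensity on a linear scale, made by the authors with Affymetrix's Statistical algorithm and scaled to a target of 500. This was checked on the values: the mean over each array without its lowest and highest 2% of probe sets was 500. The labels state neither the software version nor any other normalization, and no detection calls were used here. The table holds 45101 probe sets, of which 64 are the manufacturer's controls and were left out. Probe sets were assigned to genes with the mouse annotation table of the array: 34945 had exactly 1 symbol, 932 had several and 9160 had none listed, and probe sets without exactly 1 symbol were counted but not named.

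The labels gave each sample's line and treatment, and samples were grouped into control normoxia, control hypoxia, triCH1 normoxia and triCH1 hypoxia, 3 arrays each. Arrays were compared pairwise, and Pearson's r of the log2 signals lay between 0.93 and 0.976, with 0 identical pairs. Normoxia and hypoxia arrays with the same line name were taken as paired. The sex markers gave the same sex within each pair. After removal of group means the correlation of a pair was 0.28 in flox2_1, 0.47 in flox1, −0.02 in flox2_2, 0.58 in triCH1flox2_1, 0.54 in triCH1flox1 and 0.35 in triCH1flox2_2.

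Signals were tested as log2(signal + 20) without further normalization, for the 18903 probe sets with a mean of at least 100 over the 12 arrays (10059 genes among those with 1 symbol). The model had 1 mean per group and 8 residual degrees of freedom, and was fitted with lmFit and eBayes with a variance trend (limma 3.58.1, R 4.3.3). The 6 contrasts were the hypoxia response in control lines, the same in triCH1 lines, the difference between these responses, triCH1 against control in normoxia, triCH1 against control in hypoxia, and the mean response over both line types. Tests were two-sided, and a probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its contrast. Errors of log2 changes are standard errors from limma, and those of signals are standard deviations. In addition, the median response of each line over fixed sets of probe sets was compared between 3 control and 3 triCH1 lines by a two-sided exact permutation test over 20 assignments, whose smallest p is 0.1. For the other exact tests the number of assignments is given beside them. On simulated data, changes of 1 and 2 log2 units in 100 probe sets each were called in 54 and 96% of cases for the response in control lines, 10 and 79% for the difference in response and 42 and 92% for triCH1 against control in hypoxia.

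The gene lists were written before the data were examined, as were the contrasts, the tests, all but 1 of the alternatives and the rule for naming genes. There were 28 lists: glycolytic HIF targets, other HIF targets, HIF pathway components, the unfolded protein and integrated stress response, mitotic cell cycle, DNA replication, oxidative phosphorylation, cholesterol synthesis, p53 targets, interferon response, NF-kB genes, immediate early genes, CREB targets, collagens and matrix, contractile genes, circadian genes, histone acetyltransferases and deacetylases, ribosomal proteins, Hox genes, imprinted genes, sex markers, and markers of skeletal muscle, cartilage and bone, endothelium, macrophages, epithelium, neural cells and adipocytes. Each gene was represented by its probe set with the highest mean. Lists with at least 5 measured members (25 lists) were tested with camera in limma at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the lists within a contrast. Members were also counted after adjustment over the list alone. Named genes are, in each contrast, the 12 highest and 12 lowest called probe sets whose groups did not overlap, 1 per gene. Where fewer than 5 passed in a direction, the 5 with the smallest p that did not pass are given as such. Crebbp, Ep300, the sex markers and up to 4 members of each described list were named too, and other names are said to have been chosen after their values were seen. A gene with several probe sets is given by the one with the highest mean in its list.

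Alternatives were pseudocounts of 1 and 100, no filter and a filter at 200, quantile normalization, centring on the median, no variance trend, a robust fit, the arrays of a contrast alone, lines as blocks (fixed within a line, random between line types), the floxed gene as a covariate, lines with a floxed Ep300 allele alone, 1 value per gene, a 2-fold minimum, other choices of probe sets for the medians, and omission of each array and each line. A covariate for the sex of the line was added after the data were examined. The 12 arrays hold no stated batches.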

Results

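RNA from 12 cultures of primary mouse embryonic fibroblasts was measured on Affymetrix Mouse430_2 arrays, 1 array per culture. The fibroblasts came from e14.5 embryos and formed 6 lines. The 3 control lines each carried 1 floxed allele of a histone acetyltransferase gene. In line flox1 this was Crebbp (which encodes CBP), and in lines flox2_1 and flox2_2 it was Ep300 (which encodes p300). In the 3 triCH1 lines the CH1 domain, the part of both proteins that binds the transactivation domain of HIF-1α, was deleted from 3 of the 4 alleles, and the remaining allele was floxed. That allele was Crebbp in line triCH1flox1 and Ep300 in lines triCH1flox2_1 and triCH1flox2_2. All lines had received an adenovirus expressing Cre recombinase. Each line was cultured for 6 h in normoxia (21% O2) or hypoxia (0.1% O2), giving 4 groups of 3 arrays. The median signal of an array lay between 57.2 and 76.1 in the authors' scaled units, and the authors' scale factors lay between 2.57 and 4.28. The number of arrays, 3 per group, limits the precision of every value.

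The comparisons ask how 0.1% O2 changed the transcripts of control and triCH1 lines, and how far the response differed between them. The targeted transcripts were examined first. Signals of Crebbp (1435224_at) averaged 773 ± 24.9 (SD, n = 2 lines) in the lines with a floxed Crebbp allele and 1420 ± 404 (n = 4 lines) in those with a floxed Ep300 allele, a ratio of 0.567. The other tested Crebbp probe sets, 1436983_at and 1434633_at, gave ratios of 0.516 and 0.698, and 1459804_at, with a mean signal of 28.2, was below the filter. Ep300 (1434765_at) had the opposite direction, with 577 ± 110 (n = 2) against 338 ± 87.7 (n = 4), a ratio of 1.69. For each of these 4 probe sets the exact permutation p was 0.13 over 15 assignments of the lines, taken as independent. Crebbp (1435224_at) was close, however, in lines named alike apart from triCH1. It averaged 1735 in flox2_1 and 1804 in triCH1flox2_1, 1045 in flox2_2 and 1100 in triCH1flox2_2, and 755 in flox1 and 790 in triCH1flox1. The difference is thus not clearly one of the floxed allele. No test here paired control with triCH1 lines in that way. None of the 4 probe sets passed limma's test in any of the 6 contrasts, and probe sets of this kind do not show whether the CH1 sequence is present. The sex markers separated the lines. Eif2s3y (1417210_at), a Y-linked translation factor gene, gave 919.4 to 1821.2 in flox1, flox2_2 and triCH1flox2_1 and 1.7 to 33 in the others. Xist (1427262_at), the RNA of the inactive X chromosome, gave 299.3 to 1502.5 in flox2_1, triCH1flox1 and triCH1flox2_2 and 1.3 to 24.5 in the others. Normoxia and hypoxia arrays of a line gave the same sex in all 6 lines.

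In the control lines more probe sets were called higher than lower in hypoxia, an imbalance of the adjusted calls that unadjusted p-values did not show. The mitophagy receptor gene Bnip3 (1422470_at) rose from a signal of 723 ± 168 to 16100 ± 1440 (SD, n = 3), 21.9-fold, or 4.46 ± 0.18 on the log2 scale (SE, adjusted p = 2.12e-08). Pdk1 (1423747_a_at), whose product restrains entry of pyruvate into the citrate cycle, rose by 3.61 ± 0.27, and Ppp1r3c (1433691_at) and Ppp1r3b (1436590_at), which encode subunits that bring a protein phosphatase to glycogen, by 3.65 ± 0.39 and 2.80 ± 0.27. Egln3 (1418649_at), a prolyl hydroxylase that marks HIF-1α for destruction, rose 11.9-fold (3.58 ± 0.25), and the angiogenic factor gene Pgf (1418471_at) rose by 3.59 ± 0.54. The other top genes were Stc2 (1449484_at), a secreted glycoprotein gene, at 3.50 ± 0.30, Ankrd37 (1436538_at) at 3.41 ± 0.33, the stress-induced gene Ndrg1 (1456174_x_at) at 3.20 ± 0.18, Pfkfb3 (1416432_at), whose product makes an activator of phosphofructokinase, at 3.15 ± 0.25, Smtnl2 (1455794_at) at 3.06 ± 0.36, and the mitochondrial adenylate kinase gene Ak4 (1450387_s_at) at 2.93 ± 0.18. The 6 probe sets that fell were Spsb2 (1422106_a_at, a SOCS box protein gene, −1.19 ± 0.19), the chemokine gene Ccl7 (1421228_at, −1.19 ± 0.21), Polr1b and Polr3e (1416126_at and 1429456_a_at, subunits of RNA polymerases I and III, −0.94 ± 0.15 and −0.83 ± 0.16), Rcl1 (1416730_at, ribosomal RNA processing, −0.87 ± 0.17) and Csnk1d (1449932_at, a casein kinase gene, −0.86 ± 0.17). Of the 4 other probe sets of Csnk1d, 2 had the opposite sign, and with 1 value per gene it had −0.22 and lost its call (adjusted p = 0.974). Of 18903 probe sets 1130 had an unadjusted p under 0.05 (945 expected if none changed), 564 higher and 566 lower. With the lines as blocks 801 were higher and 977 lower at that p. Limma called 151 higher and 6 lower, in 96 and 6 genes. With the lines as blocks these became 229 and 35. The higher count was 89 without line flox2_1 and 92 without flox1. The lower count was 1, 1 and 0 without flox2_1, flox2_2 and flox1, 2 without the normoxia array of flox1, 3 without triCH1flox2_1, and 11 or 10 without triCH1flox1 or its hypoxia array. The sizes for genes with low normoxia signals depended on the pseudocount: with 100 and 1 in place of 20, Ppp1r3c had 2.20 and 4.71 and Smtnl2 1.72 and 4.08. Pgf lost its call without flox2_1 (adjusted p = 0.103) or flox2_2 (0.064), and each of the 6 lower genes lost its call under at least 1 such omission.

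Among the fixed gene lists, the HIF targets rose together in the control lines. Of the 20 measured HIF targets of glucose transport and glycolysis, 16 rose (19 adjusted over the list alone), among them the glucose transporter genes Slc2a3 (1437052_s_at, 2.75 ± 0.33) and Slc2a1 (1434773_a_at, 1.67 ± 0.18, named after its values were seen) and the lactate exporter gene Slc16a3 (1449005_at, 2.59 ± 0.23). Of the 34 other measured HIF targets 22 rose (32 adjusted over the list alone), among them Adm (1416077_at), the vasodilator peptide adrenomedullin, at 0.87 ± 0.13, also named after its values were seen. Without line flox1 Adm no longer passed (adjusted p = 0.119). Camera called both lists higher (adjusted p = 3.32e-61 and 2.35e-92, and 1.22e-03 and 1.64e-05 with an estimated correlation). Of 14 HIF pathway components 3 rose (3 adjusted over the list alone): Egln1 (1423785_at, the main HIF prolyl hydroxylase, 2.02 ± 0.15), Egln3, and Vhl (1434708_at, the ubiquitin ligase subunit that recognises hydroxylated HIF-α, 1.22 ± 0.22). That list had an adjusted p of 6.09e-04, and of 0.0382 with an estimated correlation, and Egln1 and Egln3 are on the HIF target list too. Of its 14 members 8 were positive, with a median of 0.06. Vhl missed the threshold under 6 of the 18 omissions of an array or line, each control line among them (adjusted p = 0.253, 0.0973 and 0.134 without flox2_1, flox2_2 and flox1). Of 25 genes of the unfolded protein and integrated stress response only Trib3 (1456225_x_at, a pseudokinase gene, 1.07 ± 0.23, adjusted p = 0.0492) rose over all genes, against 2 higher and 1 lower adjusted over the list alone. The list had an adjusted p of 6.46e-03, of 0.056 with an estimated correlation, of 0.0687 without flox2_1 and of 0.086 with quantile normalization. Trib3 lost its call under 16 of the 18 omissions (adjusted p between 0.0575 and 0.553). Of 18 NF-kB and inflammatory genes Ccl7 fell (2 lower adjusted over the list alone), while the chemokine gene Ccl2 (1420380_at) had −0.98 ± 0.21 and an adjusted p of 0.052. That list was called lower (adjusted p = 6.14e-03), with 0.0733 with an estimated correlation and 0.0713 without the hypoxia array of flox2_2. Camera called 12 of 25 lists and 3 with both correlations. The other 7 with the preset correlation alone were contractile genes (adjusted p = 2.77e-03, and 0.531 with an estimated correlation), ribosomal proteins (6.09e-04, then 0.559), cholesterol synthesis (0.0118, then 0.404), immediate early genes (0.0118, then 0.479), p53 targets (lower, 0.0324, then 0.404), CREB targets (0.0356, then 0.138) and circadian genes (0.0436, then 0.144).

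In the triCH1 lines hypoxia raised many of these genes as well. Bnip3 rose 20.9-fold, from 622 ± 119 to 13300 ± 1070 (SD, n = 3), or 4.39 ± 0.18 on the log2 scale (SE, adjusted p = 2.62e-08). Smtnl2 rose by 3.54 ± 0.36, Pdk1 by 3.26 ± 0.27, Stc2 by 2.81 ± 0.30, Ankrd37 by 2.78 ± 0.33, Ppp1r3b by 2.77 ± 0.27, Ak4 by 2.63 ± 0.18 and Slc16a3 by 2.47 ± 0.23. The remaining top genes were Mgarp (1420774_a_at, a mitochondrial protein gene, 2.82 ± 0.56), the lipoprotein receptor gene Vldlr (1434465_x_at, 2.57 ± 0.25), the circadian repressor gene Ciart (1435188_at, 2.56 ± 0.22) and Prelid2 (1436194_at, 2.42 ± 0.19). With pseudocounts of 100 and 1, Mgarp had 1.72 and 3.65 and Smtnl2 1.90 and 5.17, and with 1 Mgarp lost its call (adjusted p = 0.0604). Txnip (1415996_at), an inhibitor of thioredoxin and of glucose uptake, fell by 1.08 ± 0.21 (adjusted p = 0.0299). The next lowest p-values among lower genes missed the threshold: Gmppb (1439030_at) at −0.68 ± 0.14 (adjusted p = 0.0502), Spsb2 at −0.87 ± 0.19, Nol9 (1455330_at) at −0.83 ± 0.18, Rcl1 at −0.75 ± 0.17 and Armcx2 (1437849_x_at) at −0.90 ± 0.22. With 1 value per gene Spsb2 had −0.56 and Armcx2 −0.41. Of the glycolytic HIF targets 13 of 20 rose (18 adjusted over the list alone), with Slc2a3 at 2.18 ± 0.33 and Pfkfb3 at 2.12 ± 0.25. Of the other HIF targets 18 of 34 rose (28 adjusted over the list alone), with Egln3 at 2.18 ± 0.25 and Egln1 at 1.97 ± 0.15. Adm had 0.22 ± 0.13 and did not pass (adjusted p = 0.898). Both lists were called higher (adjusted p = 1.22e-46 and 1.28e-66, and 3.19e-03 and 5.92e-05 with an estimated correlation), as were the HIF pathway components (2 of 14 over all genes, 4 adjusted over the list alone, adjusted p = 7.75e-05, and 0.0199 with an estimated correlation), where Vhl had 1.02 ± 0.22 (adjusted p = 0.0567). Of these 14 components 8 were positive (median 0.13), and Egln1 and Egln3 among them are HIF targets listed above. Of 25 stress response genes Chac1 (1451382_at, a glutathione-degrading enzyme gene) rose by 1.03 ± 0.21 (adjusted p = 0.0413), and 4 higher and 2 lower passed adjusted over the list alone. That list had an adjusted p of 9.86e-03, of 0.061 with an estimated correlation, and of 0.111 and 0.0632 without triCH1flox2_2 or its hypoxia array. Chac1 lost its call under 14 of the 18 omissions (adjusted p between 0.0546 and 0.623). The contractile, cholesterol and circadian lists were called higher with the preset correlation (adjusted p = 9.86e-03, 9.86e-03 and 0.0498) and had 0.911, 0.383 and 0.158 with an estimated correlation, so that 7 of 25 lists were called and 3 of these with both. At an unadjusted p under 0.05, 610 probe sets were higher and 571 lower. Limma called 119 probe sets higher and 1 lower, in 76 genes and 1 gene. The higher count was 69 without triCH1flox2_1 and 66 without triCH1flox2_2. The lower count of 1 became 12 with the lines as blocks, 2 without triCH1flox1 or its hypoxia array, and 0 under 10 of the 18 omissions of an array or line, among them each control line. Mgarp lost its call under 15 of the 18 omissions (adjusted p up to 0.469) and Txnip under 12 (up to 0.321), and Slc2a3 lost it without triCH1flox2_1 (0.0585).

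Control and triCH1 lines shared most of the genes called higher. Of the 151 and 119 probe sets, 105 were in both sets, where 0.95 would be shared if the calls were independent, and each of the 151 and 119 had the same sign in the other line type. Across all tested probe sets, which are not independent replicates, the responses correlated with r = 0.61 (Spearman's rho 0.48). The test of the difference in response, triCH1 minus control, called 0 probe sets with limma. At an unadjusted p under 0.05 it gave 131, 63 higher and 68 lower, where 945 would be expected if no probe set differed. That model leaves out the pairing of arrays by line. With the lines as blocks 302 had an unadjusted p under 0.05, also below 945, and 0 were called. With so few small p-values the test cannot be taken at face value, and 0 calls do not show equal responses. On simulated data with independent arrays the model without pairing recovered 10% of changes of 1 log2 unit and 79% of changes of 2 log2 units. The smallest p-values among negative differences, none past the threshold (adjusted p = 1), belonged to Egln3 at −1.40 ± 0.36 (SE), Pgf at −2.75 ± 0.77, Pfkfb3 (1456676_a_at) at −1.19 ± 0.33, the phosphatidylserine synthase gene Ptdss2 (1460010_a_at) at −1.28 ± 0.36 and Ndrg1 (1423413_at) at −1.04 ± 0.29. For Ptdss2, 3 of 4 other probe sets had the opposite sign. On the positive side were Ap5s1 (1432295_a_at, 0.94 ± 0.28), Prkab2 (1435875_at, a subunit of AMP-activated kinase, 0.83 ± 0.25), Mtfr1l (1420059_at, 1.31 ± 0.40, both of its other probe sets opposite), Dnajc11 (1433881_at, 0.92 ± 0.30) and Setd6 (1428797_at, 0.71 ± 0.24). With 1 value per gene these fell to 0.52, 0.42, 0.39, 0.48 and 0.46, and Ptdss2 had −0.17. Among genes chosen after their values were seen, Adm had a difference of −0.65 ± 0.19 and Bnip3 of −0.07 ± 0.26, a sign that turned with quantile normalization (0.02).

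As groups, both HIF target lists responded less in the triCH1 lines. Of the 20 glycolytic targets 19 had a negative difference, with a median of −0.18 (adjusted p = 4.53e-07), but the call was lost with an estimated correlation (adjusted p = 0.586). The exception was Pfkfb4, which was lower in hypoxia in both line types. Of the 34 other targets 30 had a negative difference, with a median of −0.23 (adjusted p = 3.34e-10, and 0.0457 with an estimated correlation). In both lists 0 members passed singly, over all genes or adjusted over the list alone. The most negative differences were Pfkfb3 (1416432_at, −1.03 ± 0.35), Slc2a3 (−0.57 ± 0.47) and the hexokinase genes Hk2 (1422612_at, −0.44 ± 0.24) and Hk1 (1437974_a_at, −0.41 ± 0.26) in the glycolytic list, and Egln3 (−1.40 ± 0.36), Ndrg1 (1456174_x_at, −0.80 ± 0.25), Zfp395 (1452336_at, −0.73 ± 0.41) and Stc2 (−0.69 ± 0.43) in the other. Among the 18 omissions of an array or line the value nearest 0 was −0.24 for Slc2a3, −0.25 for Hk2, −0.19 for Hk1, −0.35 for Stc2 and −0.17 for the mean of the glycolytic list (−0.26 with all arrays). Zfp395 had −0.37 with a pseudocount of 100. The 4 positive ones were Plod2 (0.17), Lox (0.03), Vldlr (0.41 ± 0.36) and Rora (1424034_at, 0.49 ± 0.36), with 2 of 4 other probe sets of Vldlr and of Rora opposite. With 1 value per gene these had 0.21 and 0.23. The epithelial and keratinocyte markers, 6 of them measured, had a median difference of −0.25 (adjusted p = 0.0439, and 0.724 with an estimated correlation), with the epithelial adhesion gene Epcam (1447899_x_at) at −0.94 ± 0.46 and the keratin gene Krt19 (1417156_at) at −0.83 ± 0.34. Its call was lost in 10 of the 18 omissions of an array or line, with adjusted p between 0.0976 and 0.563. It was also lost with no variance trend (0.0528), the floxed gene as covariate (0.056), centring (0.0586), a filter at 200 (0.159) and no filter (0.71), where the list's mean went from −0.33 to −0.10. Epcam had −0.62 with a pseudocount of 100, and Krt19 lay between −1.12 and −0.54 under omissions.

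**Figure D1:**
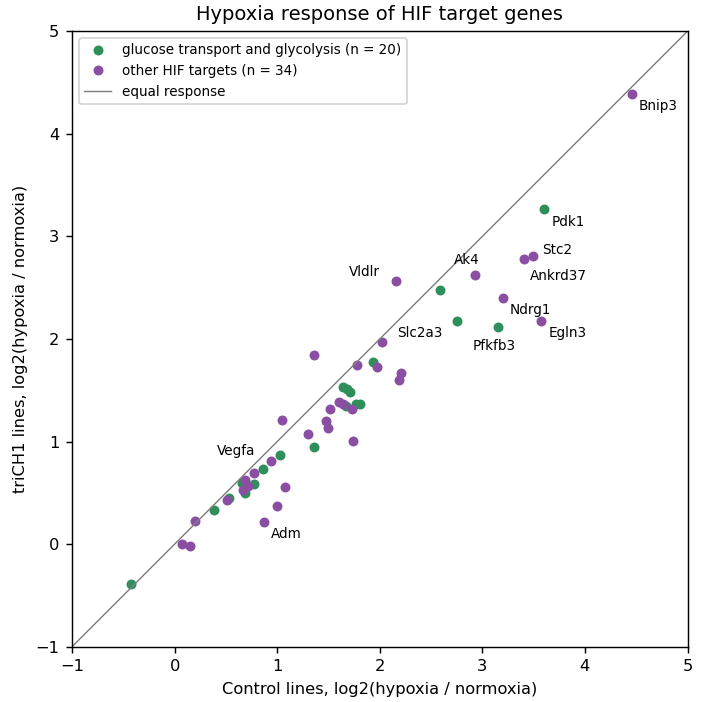
Log2 ratio of hypoxia to normoxia signal in control lines (horizontal axis) and triCH1 lines (vertical axis) for 54 HIF target genes, 1 probe set per gene, each point from 3 lines per type; the grey line marks equal responses. Most points lie below the line, Egln3 at 3.58 and 2.18 and Pfkfb3 at 3.15 and 2.12, while Bnip3 lies close to it at 4.46 and 4.39.

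The size of the response was compared line by line. Over both HIF target lists together (54 genes) the median response was 1.54 in flox1, 1.67 in flox2_1 and 1.49 in flox2_2, and 1.27 in triCH1flox1, 1.41 in triCH1flox2_1 and 1.10 in triCH1flox2_2. The means were 1.57 ± 0.10 and 1.26 ± 0.15 (SD, n = 3 lines), a difference of −0.31. All 3 triCH1 lines lay below all 3 control lines, and the two-sided exact permutation p was 0.1, the smallest that 3 against 3 lines allow. On the log2 scale the median gene reached 83.2% of its control response. On the linear scale its increase in signal reached 70.8% of that in control lines (quartiles 51.8 and 86.4%). At an equal fold change that increase is smaller where the normoxic signal is lower, so 70.8% is not a share of the fold response. Of the 54 genes, 50 had a response of smaller size in triCH1 lines, counting Pfkfb4, which fell less there. In 14 genes all 3 triCH1 lines lay below all 3 control lines and in 0 above, where chance gives 5% of genes in each direction. The genes share the same lines and are not independent, so this count adds no test beyond the p of 0.1. For the 269 probe sets called higher in the mean of both responses, the medians averaged 1.21 ± 0.02 in control and 1.07 ± 0.09 in triCH1 lines, a difference of −0.15 (exact permutation p = 0.1, n = 3 lines per type). With the probe sets chosen anew under each of the 18 omissions of an array or line, that difference was larger in size, between −0.30 and −0.17. Of the 269 probe sets 200 had the smaller response in triCH1 lines, and 49 lay below in all triCH1 lines against 4 above, with the same limit. For the 62 probe sets called lower, the medians averaged −0.65 ± 0.13 in control and −0.58 ± 0.01 in triCH1 lines, a difference of 0.06 that was smaller than the spread of the control lines (exact permutation p = 0.9, n = 3 lines per type). That last difference became −0.59 for probe sets called in the triCH1 lines alone, where 1 probe set is used, and −0.007 without triCH1flox1.

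**Figure D2:**
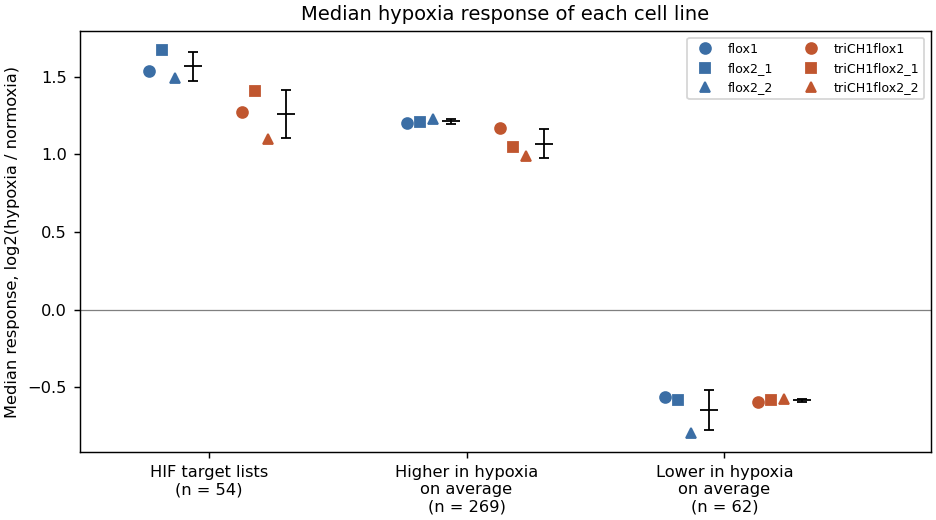
Median log2 ratio of hypoxia to normoxia signal in each of the 6 lines, for probe sets called higher (269) or lower (62) in the mean response and for the HIF target lists (54 genes); points are lines, black bars the mean and SD of 3 lines. For the HIF targets the control lines lie between 1.49 and 1.67 and the triCH1 lines between 1.10 and 1.41.

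In normoxia 1 probe set differed between triCH1 and control lines. Cthrc1 (1452968_at), a secreted protein gene of matrix remodelling, was lower in triCH1 lines, 2090 ± 314 against 5680 ± 575 (SD, n = 3), a difference of −1.44 ± 0.16 on the log2 scale (SE, adjusted p = 6.59e-03). The next lowest genes did not pass: Rgs4 (1416286_at, a regulator of G protein signalling, −1.98 ± 0.30, adjusted p = 0.0905), the natriuretic peptide gene Nppb (1450791_at, −2.16 ± 0.34, 0.0905), the imprinted gene Dlk1 (1449939_s_at, −1.21 ± 0.19, 0.0905), Ccl7 (−1.21 ± 0.21, 0.0934) and Bpgm (1415865_s_at, bisphosphoglycerate mutase, −1.19 ± 0.21, 0.0934). Nor did the genes with the smallest p on the other side, the Wnt ligand gene Wnt10a (1460657_at, 1.53 ± 0.25, 0.0934), Cotl1 (1436838_x_at, an actin-binding protein gene, 1.30 ± 0.24), Tmem176a (1423909_at, 1.15 ± 0.24), Donson (1426739_at, a replication fork protein gene, 1.00 ± 0.21) and Tmem176b (1418004_a_at, 0.98 ± 0.21). With 1 value per gene Rgs4 had −1.30 and Cotl1 0.83. Limma called 0 probe sets higher and 1 lower, while 1429 had an unadjusted p under 0.05 (945 expected if none differed). With the floxed gene as covariate the counts were 27 and 61, and in the lines with a floxed Ep300 allele alone 6 and 31. Line triCH1flox1 stood apart: without it the counts were 86 and 159, without its normoxia array 16 and 47, and without flox2_1 3 probe sets were called higher. The lower count was 6 without the hypoxia array of triCH1flox1, 3 without triCH1flox2_2, 3 with the line as a random block, and 0 without flox2_2, flox1, either of their normoxia arrays, or triCH1flox2_1, omissions that ended the call of Cthrc1 (adjusted p between 0.0521 and 0.241).

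The proliferation lists had the smallest camera p-values in normoxia with the preset correlation. All 28 measured genes of DNA replication and S phase were higher on average in triCH1 lines, with a median of 0.65. Over all genes 0 passed and adjusted over the list alone 18 did, among them the replication licensing genes Cdc6 (1417019_a_at, 1.29 ± 0.42), Cdt1 (1424143_a_at, 1.13 ± 0.32) and Mcm3 (1420028_s_at, 1.03 ± 0.25) and the maintenance methylation factor gene Uhrf1 (1415810_at, 1.07 ± 0.25). All 24 mitotic genes had positive values too, with a median of 0.45, and 0 passed over all genes or adjusted over the list alone. Examples were the kinase gene Aurkb (1424128_x_at, 0.84 ± 0.28) and the cyclin gene Ccna2 (1417911_at, 0.67 ± 0.31). Camera called both lists higher (adjusted p = 7.65e-20 and 4.27e-12), and neither with an estimated correlation (adjusted p = 0.156 for each). By line, the DNA replication list stood at −0.50, −0.36 and −0.15 in flox1, flox2_1 and flox2_2, and at −0.07, 0.65 and 0.50 in triCH1flox1, triCH1flox2_1 and triCH1flox2_2 (exact permutation p = 0.1, n = 3 lines per type, the smallest possible). On the mitotic list the line types overlapped, with triCH1flox1 at −0.096 below flox2_2 at −0.064 (exact permutation p = 0.2, n = 3 lines per type). Of 22 p53 targets 18 were lower, with 0 past the threshold over all genes and 2 adjusted over the list alone, the pro-apoptotic gene Pmaip1 (1418203_at, −2.17 ± 0.53) and the stress-induced gene Trp53inp1 (1416926_at, −0.94 ± 0.24) (adjusted p = 2.82e-06, and 0.116 with an estimated correlation). The other HIF targets were lower already in normoxia, 26 of 34, with 2 adjusted over the list alone (adjusted p = 1.85e-05, and 0.116 with an estimated correlation), with Ankrd37 at −1.70 ± 0.33 among these 2. Egln3, at −0.75 ± 0.25, did not pass, and with 1 value per gene it had −0.45. Further lists were called lower with the preset correlation: contractile genes (3 adjusted over the list alone, such as the smooth muscle genes Actg2, 1422340_a_at, −1.27 ± 0.33, and Mylk, 1425506_at, −0.89 ± 0.20, adjusted p = 1.88e-04, and 0.389 with an estimated correlation), cartilage and bone markers (2 of 6 adjusted over the list alone, with the cartilage collagen genes Col10a1, 1422253_at, −2.33 ± 0.52, and Col2a1, 1450567_a_at, −2.23 ± 0.54, adjusted p = 1.61e-03, then 0.162, and 0.0858 without a filter, where the mean went from −0.92 to −0.31), NF-kB genes (2 adjusted over the list alone, with Il11, 1449982_at, at −1.37 ± 0.31, adjusted p = 4.06e-03, then 0.116), collagens (4.06e-03, then 0.37), imprinted genes (0.0165, then 0.137) and neural markers (0.0228, then 0.144). The contractile list lost its call without flox1 (adjusted p = 0.13) or its normoxia array (0.108). It did not separate the line types, as control line flox2_1 was the lowest of the 6 lines at −0.206 (exact permutation p = 0.6, n = 3 lines per type). Camera thus called 10 of 25 lists, and 0 with an estimated correlation.

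**Figure D3:**
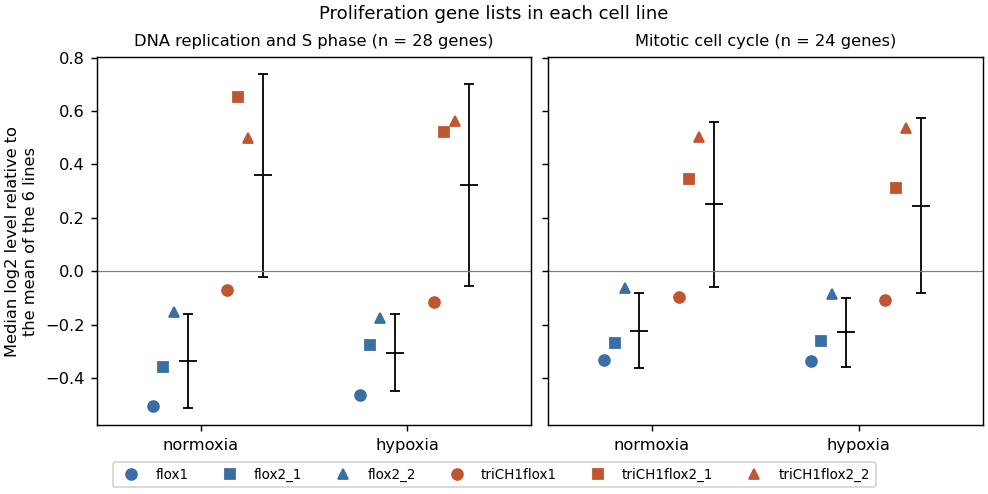
Median log2 level of the 28 DNA replication and 24 mitotic genes in each line, relative to each gene's mean over the 6 lines under the same treatment; points are lines, black bars the mean and SD of 3 lines. For DNA replication in normoxia triCH1flox2_1 and triCH1flox2_2 lie at 0.65 and 0.50, triCH1flox1 at −0.07, and the control lines between −0.50 and −0.15.

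In hypoxia 14 probe sets differed between triCH1 and control lines, 2 of them listed HIF targets (Egln3 and Ankrd37). Pgf was lower in triCH1 lines, with a signal of 63.7 ± 71.7 against 655 ± 100.0 (SD, n = 3), a log2 difference of −3.37 ± 0.54 (SE, adjusted p = 0.0391). Egln3 stood at 1360 ± 385 against 5980 ± 734, a difference of −2.15 ± 0.25 (adjusted p = 6.77e-03), and Ankrd37 at −2.33 ± 0.33 (0.027). Cthrc1 was again lower (−1.44 ± 0.16, adjusted p = 6.31e-03), and so were the chemokine-scavenging receptor gene Ackr3 (1417625_s_at, −2.24 ± 0.34), Nppb (−2.22 ± 0.34), the small GTPase genes Rasl11b (1423854_a_at, −2.27 ± 0.33) and Gem (1426063_a_at, −1.57 ± 0.25), AA467197 (1434046_at, −3.13 ± 0.52), Srpx2 (1427919_at, −2.80 ± 0.47), Bpgm (−1.43 ± 0.21), the antiproliferative gene Btg1 (1437455_a_at, −1.07 ± 0.16) and, named after its values were seen as the last of the 13, the lipid droplet gene Hilpda (1421031_a_at, −0.98 ± 0.16). With pseudocounts of 100 and 1, AA467197 had −1.80 and −4.44, Srpx2 −1.56 and −3.93 and Pgf −2.28 and −4.09. All 3 lost their calls with 1 (adjusted p = 0.111, 0.111 and 0.136), and Srpx2 also with 100 (0.0514). Wnt10a was higher (1.61 ± 0.25, adjusted p = 0.0391). The next smallest p among higher genes missed the threshold: Plekhg5 (1452248_at, 1.15 ± 0.22), the innate immune adaptor gene Sting1 (1427911_at, 1.02 ± 0.21), Grwd1 (1452171_at, a ribosome biogenesis factor gene, 0.71 ± 0.15), Polr1b (0.71 ± 0.15) and Tmem176a (1.07 ± 0.24). Limma called 1 probe set higher and 13 lower, with 1506 at an unadjusted p under 0.05 (945 expected if none differed). With the floxed gene as covariate the counts were 26 and 103, and in the lines with a floxed Ep300 allele alone 8 and 35. Without triCH1flox1 the counts were 94 and 182. The other line omissions left 0 to 2 higher and 0 to 5 lower, and all but 3 of the 12 single-array omissions left 6 or fewer lower. Cthrc1 lost its call without flox2_2 (0.0638), flox1 (0.104) or the hypoxia array of triCH1flox2_1 (0.0558). Egln3 lost its call without flox2_1 (0.101), flox2_2 (0.0638), flox1 (0.104) or triCH1flox2_2 (0.113), or without the hypoxia array of flox2_1 (0.0849), triCH1flox2_1 (0.0558) or triCH1flox2_2 (0.0742). The other 12 called genes each lost the call under at least 8 of the 18 omissions. Across all tested probe sets the normoxia and hypoxia differences correlated with r = 0.66 (rho 0.57), with the same lines behind both.

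Of the 34 other HIF targets, 2 were lower over all genes and 17 adjusted over the list alone, with a median of −0.45 (adjusted p = 5.83e-17, and 8.98e-03 with an estimated correlation). Members that did not pass over all genes included Ndrg1 (−1.03 ± 0.18, adjusted p = 0.0632), the secreted hormone gene Stc1 (1450448_at, −1.06 ± 0.28) and Adm (−0.69 ± 0.13, 0.0954). By line the list stood at 0.28, 0.22 and 0.23 in flox1, flox2_1 and flox2_2 and at −0.10, −0.24 and −0.41 in triCH1flox1, triCH1flox2_1 and triCH1flox2_2 (exact permutation p = 0.1, n = 3 lines per type, the smallest possible). Of the glycolytic targets 0 of 20 passed over all genes and 2 adjusted over the list alone, Slc2a3 at −1.31 ± 0.33 and Pfkfb3 at −1.15 ± 0.25, while Slc2a1 had −0.54 ± 0.18 (adjusted p = 1.13e-04, and 0.239 with an estimated correlation). On that list the line types overlapped, with triCH1flox1 at 0.06 above flox2_2 at 0.02 (exact permutation p = 0.2, n = 3 lines per type). All 28 DNA replication genes (median 0.67, 13 adjusted over the list alone) and all 24 mitotic genes (median 0.45, 0 adjusted over the list alone) were higher on average, with Cdt1 at 1.11 ± 0.32, Mcm5 (1436808_x_at) at 0.89 ± 0.26 and the proliferation marker Mki67 (1426817_at) at 0.81 ± 0.42. Their adjusted p were 3.69e-13 and 9.17e-11, and 0.231 and 0.2 with an estimated correlation. Compared by line, the exact permutation p was 0.1 for the DNA replication list and 0.2 for the mitotic list (n = 3 lines per type). The interferon response list was called higher, with 12 of 14 positive and 3 adjusted over the list alone (adjusted p = 0.0107, and 0.239 with an estimated correlation), with the antigen peptide transporter gene Tap1 (1416016_at) at 1.68 ± 0.38 and the antiviral gene Oas1a (1424775_at) at 1.58 ± 0.49. That call was lost without triCH1flox2_1 (adjusted p = 0.0867) or its hypoxia array (0.0851), and with a filter at 200 (0.0761). With a pseudocount of 100 Tap1 had 0.86 and Oas1a 0.93. Lists called lower with the preset correlation alone were contractile genes (adjusted p = 1.34e-04, and 0.408 with an estimated correlation), cartilage and bone markers (1.66e-03, then 0.2, with Col2a1 at −2.69 ± 0.54), p53 targets (1.66e-03, then 0.2), collagens (0.0251, then 0.44), CREB targets (0.0329, then 0.2), imprinted genes (0.0499, then 0.2) and neural markers (0.0499, then 0.2). Compared by line (n = 3 per type), the exact permutation p was 0.3 for contractile genes and 0.4 for collagens. It was 0.2 for cartilage markers, p53 targets and imprinted genes, and 0.1 for CREB targets and neural markers. In all, 12 of 25 lists were called and 1 with an estimated correlation.

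Averaging both line types gave the largest number of hypoxia-responsive genes. Bnip3 rose by 4.42 ± 0.13 (SE, n = 6 lines, adjusted p = 2.19e-10), Pdk1 by 3.43 ± 0.19, Smtnl2 by 3.30 ± 0.25, Stc2 by 3.15 ± 0.21, Ankrd37 by 3.09 ± 0.24, Ppp1r3c by 3.02 ± 0.28, Egln3 by 2.88 ± 0.18, Ndrg1 by 2.80 ± 0.13, Ppp1r3b by 2.79 ± 0.19, Ak4 by 2.78 ± 0.13 and Pfkfb3 by 2.63 ± 0.18. The MHC class II gene H2-Ab1 (1450648_s_at) rose by 2.80 ± 0.45 from low signals. With pseudocounts of 100 and 1 it had 1.61 and 3.81, Smtnl2 1.81 and 4.62 and Ppp1r3c 1.67 and 4.26. Genes that fell included Spsb2 (−1.03 ± 0.13), the DNA repair genes Ercc8 (1432249_a_at, −0.96 ± 0.17) and Apex2 (1425954_a_at, −0.76 ± 0.17), the calcium channel gene Orai1 (1424989_at, −0.90 ± 0.17), the NF-kB inhibitor gene Nfkbie (1431843_a_at, −0.90 ± 0.19), the RNA-binding protein gene Zfp36l1 (1422528_a_at, −0.88 ± 0.19), Rcl1 (−0.81 ± 0.12), the cell cycle phosphatase gene Cdc25a (1417132_at, −0.78 ± 0.17), Polr1b (−0.74 ± 0.11), Gpd1l (1438195_at, −0.72 ± 0.15), the mitochondrial import gene Chchd4 (1417233_at, −0.71 ± 0.14) and the antioxidant gene Srxn1 (1425351_at, −0.70 ± 0.16). With 1 value per gene Ercc8 had −0.63 and Apex2 −0.51. At an unadjusted p under 0.05, 905 probe sets were higher and 1233 lower (1353 and 1809 with the lines as blocks). The balance thus turned with the threshold. Limma called 269 probe sets higher and 62 lower, in 176 and 49 genes, of which 148 and 1 changed at least 2-fold. With the lines as blocks the counts were 455 and 238. The higher count was 179 without triCH1flox2_2. The lower count fell to between 11 and 40 under 15 of the 18 omissions of an array or line, every line among them, and was lowest at 11 without flox2_2 and 13 without flox1. Calls among the lower genes were lost under 16 of these omissions for Zfp36l1, 15 for Apex2, 14 each for Cdc25a, Nfkbie and Srxn1, 12 for Gpd1l, 5 for Orai1 and 3 each for Ercc8 and Chchd4 (adjusted p up to 0.212).

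In that mean response 16 of 20 glycolytic HIF targets rose (19 adjusted over the list alone) and 28 of 34 other targets (32 adjusted over the list alone), with adjusted p of 1.93e-50 and 2.08e-75, and 2.43e-03 and 3.65e-05 with an estimated correlation. Of 14 HIF pathway components 3 rose (4 adjusted over the list alone, adjusted p = 3.14e-04, and 0.0302 with an estimated correlation), Egln1 by 2.00 ± 0.11, Vhl by 1.12 ± 0.16, and Egln3. Of 25 unfolded protein and integrated stress response genes 6 rose and 1 fell (8 and 2 adjusted over the list alone, adjusted p = 3.18e-03, and 0.0377 with an estimated correlation). Chac1 rose by 0.82 ± 0.15, Trib3 by 0.81 ± 0.16 and the serine hydroxymethyltransferase gene Shmt2 (1455084_x_at) by 0.63 ± 0.13, with 1 of 3 other Shmt2 probe sets opposite. Vegfa (1420909_at), the endothelial growth factor gene that is on this list and among the HIF targets, had 0.88 ± 0.22 and did not pass (adjusted p = 0.0746). Of 22 cholesterol synthesis genes Hmgcs1 (1433445_x_at, 0.55 ± 0.11) and the squalene epoxidase gene Sqle (1415993_at, 0.47 ± 0.11) rose (4 adjusted over the list alone, adjusted p = 3.7e-03, and 0.282 with an estimated correlation). Of 18 NF-kB genes the chemokine genes Ccl2 and Ccl7 fell by 0.83 ± 0.15 each (2 adjusted over the list alone, adjusted p = 0.0172, and 0.132 with an estimated correlation). Single calls were lost under 16 of the 18 omissions for Sqle (adjusted p up to 0.194), 12 for Shmt2 (0.157), 10 each for Hmgcs1 (0.103) and Trib3 (0.133), 3 each for Chac1 and Ccl2 and 1 for Ccl7. The calls of the cholesterol and NF-kB lists were lost without flox2_1 (adjusted p = 0.0533 each) or its normoxia array (0.0797 for cholesterol synthesis and 0.0706 for NF-kB). Contractile genes (adjusted p = 1.17e-03, and 0.598 with an estimated correlation), ribosomal proteins (2.96e-03, then 0.711), immediate early genes (0.027, then 0.598) and circadian genes (0.035, then 0.132) were called higher with the preset correlation alone. Of the lists not called here, CREB targets had an adjusted p of 0.0777, p53 targets 0.126, Hox genes 0.166, the interferon response 0.285, DNA replication 0.423, macrophage and epithelial markers 0.47 each, oxidative phosphorylation and imprinted genes 0.653 each, the mitotic cycle and skeletal muscle markers 0.797 each, neural markers 0.903, histone acetyltransferases and deacetylases 0.907, collagens 0.98 and cartilage markers 0.984. Oxidative phosphorylation, histone acetyltransferases and deacetylases, Hox genes, and skeletal muscle and macrophage markers were called in none of the 6 contrasts. Endothelial and adipocyte markers, with 4 and 3 measured members, were too few for camera.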

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

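The tests of explanations given here were all chosen after the smaller response of the HIF targets had been seen. The difference in hypoxia response between line types was tested for 25 gene lists, and 3 lists differed by camera with the preset correlation. The 20 glycolytic HIF targets had a median difference, triCH1 minus control, of −0.177 (adjusted p = 4.53e-07, and 0.586 with an estimated correlation), and 19 of 20 were negative. The 34 other HIF targets had a median of −0.23 (adjusted p = 3.34e-10, and 0.0457 with an estimated correlation), and 30 of 34 were negative. The 6 epithelial and keratinocyte markers had a median of −0.248 (adjusted p = 0.0439, and 0.724 with an estimated correlation), and 4 of 6 were negative, a call lost under 10 of the 18 omissions of an array or line and under 5 processing alternatives (adjusted p up to 0.71). Groups of 3 arrays were not tested for single arrays far from the rest.

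For the HIF targets, a higher starting level in triCH1 normoxia could shrink the response, but the 54 genes stood at −0.116 ± 0.084 (SE, log2) in normoxia relative to control and at −0.364 ± 0.087 in hypoxia, so that the smaller response lay in the hypoxic level. The arrays had already been scaled to the same target, so only a scaling difference left after that could be tested. Such a difference would move all probe sets, yet the median over all tested probe sets was 0.0081. With quantile normalization the difference in response was −0.26, against −0.31 without it. Both line types held both sexes: 2 of 3 control lines and 1 of 3 triCH1 lines had Y-linked transcripts. Among lines with these transcripts the median response was 1.41 in triCH1flox2_1 against 1.54 in flox1 and 1.49 in flox2_2. Among the others it was 1.27 in triCH1flox1 and 1.10 in triCH1flox2_2 against 1.67 in flox2_1. With sex in the model the difference was −0.295 ± 0.13, near the −0.31 without it. Its 95% interval, from −0.699 to 0.109 at 3 residual degrees of freedom, included 0, so the lines are too few to exclude a contribution of sex. The deletion of the CH1 domain, which the design names, remains open beside sex and the history of each line.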

How the results depend on the processing

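The sex covariate was chosen after the data were seen, and the other alternatives before. For the changes below the cause was not tested, except that the 2-fold minimum and 1 value per gene shrink a count by construction, omissions leave fewer samples, and choosing probe sets on the triCH1 response favours it. The difference in response had 0 calls under all 31 alternatives. The list of other HIF targets kept its lower response under all its alternatives with the preset correlation. With an estimated correlation its adjusted p was 0.0457, the highest. That correlation was used with the main settings alone, so this narrow call was not tried under omissions. The glycolytic HIF list kept its direction but lost its call with an estimated correlation (mean −0.26). Called higher and lower in the control response (151 and 6), the counts were 94 (higher) with 1 value per gene, 229 and 35 with blocks, and for the lower count 2 at 2-fold, 10 with a robust fit, 10 with pseudocount 100 and 17 with the floxed gene as covariate; omissions gave 89 to 170 and 0 to 11. In the triCH1 response (119 and 1) they were 77 and 2 per gene, and the lower count was 12 with blocks, 5 with the covariate, 2 with a robust fit, pseudocount 100 or a filter at 200, and 0 with the contrast's own arrays, no trend or centring; omissions gave 66 to 120 and 0 to 2. In the mean response (269 and 62) they were 175 (higher) per gene, 148 and 1 at 2-fold, 455 and 238 with blocks, and for the lower count 148 with the covariate and 34 with centring; omissions gave 179 to 265 and 11 to 62. For triCH1 against control in normoxia (0 and 1) they were 27 and 61 with the floxed gene as covariate, 6 and 31 in the flox2 lines alone, and for the lower count 9 with the sex covariate, 3 with blocks, 2 with centring or quantile normalization, and 0 with own arrays or no trend; omissions gave 0 to 86 and 0 to 159. In hypoxia (1 and 13) they were 26 and 103 with the covariate, 8 and 35 in the flox2 lines alone, 0 and 6 with own arrays, 0 and 2 with no trend, 2 (higher) per gene, 0 (higher) with the sex covariate and 22 (lower) with centring; omissions gave 0 to 94 and 0 to 182. Median differences in response under omissions were −0.30 to −0.17 for higher probe sets, −0.0066 to 0.28 for lower ones and −0.38 to −0.23 for HIF targets; the lower set reversed to −0.59 for the probe set called in triCH1 lines. The difference of Bnip3 (−0.07) reversed to 0.025 with quantile normalization and lay between −0.29 and 0.11 under omissions. Of 97 called gene results, 46 kept their call under every alternative and 51 lost it under at least 1. The filter at 200 left too few cartilage markers for a value. Signals near background limit low genes such as Pgf, Ppp1r3c, Smtnl2, Mgarp, H2-Ab1, AA467197 and Srpx2.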

Other observations

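The genes of the line comparison, the tests on proliferation genes and the 3 added gene lists were chosen after results had been seen, whereas the outcomes looked for in the 3 lists and in the splits were written down before those tests. The triCH1flox2_1 and triCH1flox2_2 lines, compared without triCH1flox1 against the 3 control lines, differed in normoxia at 245 probe sets in 187 genes (limma). Genes of DNA replication were higher: Cdc6 by 1.71 ± 0.29 (log2, SE), Cdt1 by 1.54 ± 0.22 and the polymerase gene Pold1 by 1.41 ± 0.24. Of 28 DNA replication genes 14 were called higher, and of 24 mitotic genes 4 (adjusted p = 3.26e-26 and 8.15e-16, and 0.0496 with an estimated correlation for each). On the DNA replication list the omitted triCH1flox1 stood at −0.07, against 0.65 in triCH1flox2_1 and 0.50 in triCH1flox2_2. Leaving it out therefore enlarges the difference, and these calls are not separate support for it. The list of 34 other HIF targets was called lower, with 2 genes called and 10 positive (adjusted p = 1.21e-05, and 0.0496 with an estimated correlation). There triCH1flox1 stood at 0.02, against −0.15 in triCH1flox2_1 and −0.22 in triCH1flox2_2, so the same limit holds. Marker lists of other cell types were called with the preset correlation alone, epithelial markers higher (6 of 6 positive, adjusted p = 0.0258, then 0.255) and neural (0.0258, then 0.199), skeletal muscle (0.033, then 0.336) and cartilage markers (0.0401, then 0.417) lower. The chromatin remodeller gene Hells (1.62 ± 0.35), the hindlimb transcription factor gene Pitx1 (1.39 ± 0.28) and the keratin gene Krt18 (1.43 ± 0.26) were higher as well. Lower were Plac8 (−3.48 ± 0.40), the keratinocyte envelope genes Lce1f (−3.27 ± 0.43) and Crct1 (−2.89 ± 0.36), Itgbl1 (−3.01 ± 0.23), Pmaip1 (−2.66 ± 0.37), Rgs16 (−2.63 ± 0.45), Nppb (−2.62 ± 0.23), the matrix gene Edil3 (−2.59 ± 0.43), the fibroblast surface gene Lrrc15 (−2.46 ± 0.37) and the actin-bundling gene Synpo2 (−2.40 ± 0.39).

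In hypoxia the same comparison called 276 probe sets in 202 genes. The matrix proteoglycan gene Dcn was higher by 2.78 ± 0.62, the cytokine gene Tslp by 2.57 ± 0.57, the growth arrest gene Gas1 by 1.97 ± 0.42, Pitx1 by 1.91 ± 0.28 and the replication initiation gene Mcm10 by 1.64 ± 0.29. Pgf was lower at −4.04 ± 0.47, Col2a1 at −3.14 ± 0.55, the transcription factor gene Sox11 at −2.78 ± 0.58 and the MAP kinase phosphatase gene Dusp4 at −2.64 ± 0.31. Of the DNA replication genes 12 were called higher and of the mitotic genes 3. Camera gave these lists adjusted p of 9.92e-20 and 3.97e-14, and 0.0732 each with an estimated correlation. Of the 34 other HIF targets 10 were called lower, and 3 of the 20 glycolytic ones (adjusted p = 3.97e-14 and 3.8e-05, and 7.64e-03 and 0.279 with an estimated correlation). On the other HIF targets the omitted triCH1flox1 stood at −0.10, against −0.24 in triCH1flox2_1 and −0.41 in triCH1flox2_2. On the glycolytic ones it stood at 0.06, against −0.21 and −0.05, and on the DNA replication list at −0.11, against 0.52 and 0.56. Leaving it out therefore enlarges these differences, and these calls are not separate support for them. The floxed allele, the line and the genotype coincide for triCH1flox1, the only line of its genotype.

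The DNA replication list was higher in triCH1 lines in normoxia, by 0.697 ± 0.24 (SE) between line types. The values argued against 1 line as the whole cause and against a shift of all probe sets left after the authors' scaling. Omitting 1 triCH1 line at a time left between 0.551 and 0.912. The median over all tested probe sets was 0.016, and with quantile normalization the list stood at 0.712. With sex in the model the difference was 0.775 ± 0.26, larger than without it, with a 95% interval from −0.0628 to 1.61. Both line types held both sexes, but the interval included 0, so the lines are too few to exclude a contribution of sex. Genotype and differences between lines in growth stay open and were not tested separately.

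Because Polr1b and Rcl1 had fallen in hypoxia, a hypothesis was that other ribosome biogenesis genes may be lower too. A list of 52 such genes, without those already seen, had 51 measured, of which 45 were negative in the mean response (median −0.19), 0 called over all genes and 10 adjusted over the list alone, among them Rrp12 (−0.56 ± 0.14), Polr1a (−0.53 ± 0.16) and Nop56 (−0.38 ± 0.12). Camera gave an adjusted p of 3.96e-07 with the preset correlation but 0.378 with an estimated correlation, so the question stays open. For triCH1 against control the same genes were positive in 49 of 51 cases in normoxia (median 0.19, adjusted p = 2.37e-06, and 0.332 with an estimated correlation) and in 50 of 51 in hypoxia (median 0.30, adjusted p = 2.53e-10, then 0.233). The rise of Ppp1r3b and Ppp1r3c led to a list of other glycogen metabolism genes (13 measured), and that of the histone demethylase genes Kdm3a (1.85 ± 0.12) and Kdm4b (1.42 ± 0.17), both on the list of other HIF targets, to a list of other Jumonji demethylases (16 measured). Neither list was called higher (adjusted p = 0.0873 and 0.213).

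Other splits of the arrays were counted. For the mean response, 1 of 100 splits, the real one with 331 calls, gave as many, the highest other gave 8, and the highest among 12 others that also part all 6 pairs gave 0. When arrays were exchanged within lines, 1 of 32 arrangements gave as many, and the highest other gave 1. These shares, the smallest that the 100 splits and 32 arrangements allow, make chance an unlikely source of that count. They cannot separate hypoxia from anything else that differed between normoxia and hypoxia arrays. For contrasts of 3 against 3 arrays or lines, 10 splits are too few for a share under 0.05. There 1 of 10 splits, the real one, was as large in the control response (157 calls, highest other 0), the triCH1 response (120, highest other 0), triCH1 against control in normoxia (1, highest other 0) and in hypoxia (14, highest other 0), and 10 of 10 in the difference in response (0, highest other 0).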
